A study of Gallus gallus with 9 samples.

How the data were processed

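Total RNA was extracted with TRIzol from cultured chicken cells and biotin-labelled cRNA was made from 5 ug of it for one Affymetrix chicken array per sample, per the labels. The deposited values were log2 expression values, 1 per probe set (a group of probes on the array that read one transcript), made by the authors from the scanned arrays. GCRMA, which corrects background by probe sequence, normalizes the arrays together and summarizes the probes of each set, was named per the submitters' processing notes; its version was not given in the sources used here. The values reached 16.01 at most and had the shape of the log2 scale, and were used as deposited with no further scaling. Because GCRMA pulls dim probe sets towards a common low level, differences between dim probe sets are compressed and a gene near that level has no reliable rank.

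The table held 38535 probe sets on 9 arrays in 3 groups of 3. The 96 control probe sets were left out of all tests and looked at separately. A probe set was tested when it reached log2 4 on at least 3 arrays, which left 16727 of 38439. The array's annotation listed 27355 probe sets, and 26863 of these had a gene number that the RefSeq gene table of assembly GRCg7b also held, from which current symbols were taken. That assembly was used only for gene names, chromosome membership and gene order, and no coordinates from it are given. Of the probe sets tested, 13807 carried 1 gene symbol, 79 carried several and were not named, and 2841 carried none, which left 8078 genes. Where a gene had several probe sets, the one with the highest mean over all 9 arrays was used.

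Groups were taken from the labels, which call the 3 arrays of each line biological replicates. The p-values therefore measure the spread between arrays of the same line, not between separate lines of the same kind. For arrays, the depth cannot be stated as a count; their number, 3 per group, limits the precision. Pairs of arrays of a group held exactly equal deposited values at 114 to 231 of the 16727 probe sets tested, so no array was a copy of another. The 3 pairwise differences between lines were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) on all 9 arrays, with 6 residual degrees of freedom, and a probe set was called when its Benjamini-Hochberg adjusted p lay under 0.05. Every adjusted p given for a gene comes from that fit. EGR1 was also tested by a two-sided exact permutation test, which cannot give a p under 0.1 with 3 arrays against 3. Errors are standard deviations (SD) over 3 arrays for levels, and standard errors (SE) of the fit for differences.

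A group of arrays in which a gene stayed under log2 4 throughout, or on average, gives only a bound. The difference was then computed as the brighter group's mean minus 4 and is written as "at least"; such genes are not ranked by these bounds, and no size is given where both groups lay under 4. Levels of different probe sets are not set against each other, since probes differ in brightness.

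Genes were named by a rule: EGR1, then for each comparison the 10 genes with the largest fitted rise and the 10 with the largest fitted fall, values under log2 4 included as deposited, among called genes whose 3 arrays in one group all lay above or all below those of the other, then up to 4 called members of each gene list with the largest differences. Not every gene that the rule allows is named, and some results are not reported here. Genes outside the rule are said to be so. The 23 gene lists were written from general knowledge of v-src transformed fibroblasts, EGR1, metastasis and markers of other cell types, and none was chosen on these samples. The lists, the rule, the tests of the comparisons and all but 1 of their alternatives were chosen before the data were examined. Each list was tested against all other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 23 lists, and again with the correlation estimated from the data, with which none of the 10 list calls held. Counts of members that rose or fell use the adjustment over all probe sets, with counts adjusted over the list alone beside them.

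Both metastatic lines were compared with the same 3 PR9692-E9 arrays. The overlap of the calls was therefore set beside that of 100 simulations of unchanged groups against shared controls, and beside the product expected of independent lists. The test was tried on simulated data with 200 changed probe sets among 16727, in 10 runs per comparison. For PR9692 against PR9692-E9 it recovered 26.3% of changes of 1 on the log2 scale and 70.2% of changes of 2, and 4.74% of its calls were false. For PR9692-E9-EGR1 against PR9692-E9 these were 23.8%, 71.4% and 5.93%, and for PR9692-E9-EGR1 against PR9692 25.0%, 72.2% and 5.45%. The list test, run on 8078 genes, called a list of 25 members shifted by 1 in 10 of 10 runs of each comparison, and 0 of 220 unshifted lists. The noise in the runs of both tests was independent between genes, with a spread pooled over the groups. These rates therefore do not cover correlated genes, unequal spread or an outlying array. In the data, the correlation estimated within a list reached 0.597, for cholesterol and lipid synthesis. Alternatives covered the filter, the scaling between arrays, a replicate block, the arrays in the fit, the moderation of variances, array weights, the threshold, the probe set used per gene and the omission of each array in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.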

Results

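Chicken Affymetrix arrays measured RNA from 3 related sarcoma cell lines transformed by v-src, the oncogene of Rous sarcoma virus. PR9692 was the parent line and highly metastatic, and PR9692-E9 was a clone of it that had lost metastatic ability. PR9692-E9-EGR1 was that clone after infection with a replication-defective retrovirus carrying the EGR1 cDNA, and its label gave it as metastatic. EGR1 is an immediate early zinc finger transcription factor. Each line had 3 arrays, and no line infected with an empty vector was analysed here. The arrays are replicates of a single line each. Effects of EGR1 or of metastatic ability therefore cannot be told apart from other differences between the lines. Each array held between 15947 and 16379 probe sets at log2 4 or more, and array medians lay between 2.99 and 3.06. PR9692-E9 replicate 3 stood apart from its group, with a mean correlation of 0.932 with the other arrays of its line against 0.953 and 0.964 for replicates 2 and 1. Its actin probe sets also differed most between the 3' and 5' ends (1.92 on the log2 scale, against 1.32 to 1.77 on the other arrays). The GAPDH probe sets did not set it apart in this way (-0.25, against -0.30 to -0.17 on the other arrays).

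EGR1 was higher in PR9692 than in either other line. Its level was 13.67 ± 0.66 (log2, SD, n = 3) in PR9692, 9.62 ± 1.24 in PR9692-E9 and 10.82 ± 1.42 in PR9692-E9-EGR1. The 3 PR9692 arrays read 13.69, 12.99 and 14.31, the PR9692-E9 arrays 10.32, 10.35 and 8.18, and the PR9692-E9-EGR1 arrays 10.24, 12.44 and 9.78. PR9692 lay above PR9692-E9 by 4.05 ± 0.80 (SE; 95% interval 2.23 to 5.86; adjusted p = 0.0153), which is 16.5-fold. PR9692-E9-EGR1 lay above PR9692-E9 by 1.20 ± 0.80 (interval -0.61 to 3.02; adjusted p = 0.294), which was within the spread between replicates, and below PR9692 (-2.84 ± 0.80; adjusted p = 0.0247). The other probe set of EGR1 gave 12.31 ± 0.66, 8.05 ± 1.23 and 8.53 ± 1.60 in the same order of lines, with differences of 4.27 (adjusted p = 0.0160), 0.48 (adjusted p = 0.709) and -3.79 (adjusted p = 0.0101). Exact permutation tests of the main probe set gave p = 0.1, 0.6 and 0.1, where 0.1 is the smallest p that 3 arrays against 3 allow. The call between PR9692 and PR9692-E9 was lost without PR9692 replicate 3 (3.73, adjusted p = 0.0668), and that between PR9692-E9-EGR1 and PR9692 without PR9692 replicate 1 (adjusted p = 0.0595) or 3 (0.0858) or PR9692-E9-EGR1 replicate 1 (0.0750) or 3 (0.0919). With no filter on level these calls had adjusted p = 0.0767 and 0.106. PR9692 lay above PR9692-E9 by 3.33 without PR9692-E9 replicate 3, and PR9692-E9-EGR1 then lay above it by 0.49. Without PR9692-E9-EGR1 replicate 2 that line lay above PR9692-E9 by 0.39 and differed from PR9692 by -3.66. Array weights turned the difference between PR9692-E9-EGR1 and PR9692-E9 to -0.30 (adjusted p = 0.457) and gave 3.37 and -3.67 for the others. Whether the EGR1 probes lie within the cDNA carried by the vector was not given in the sources used here, so these values do not check the label of the infected line.

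**Figure D1:**
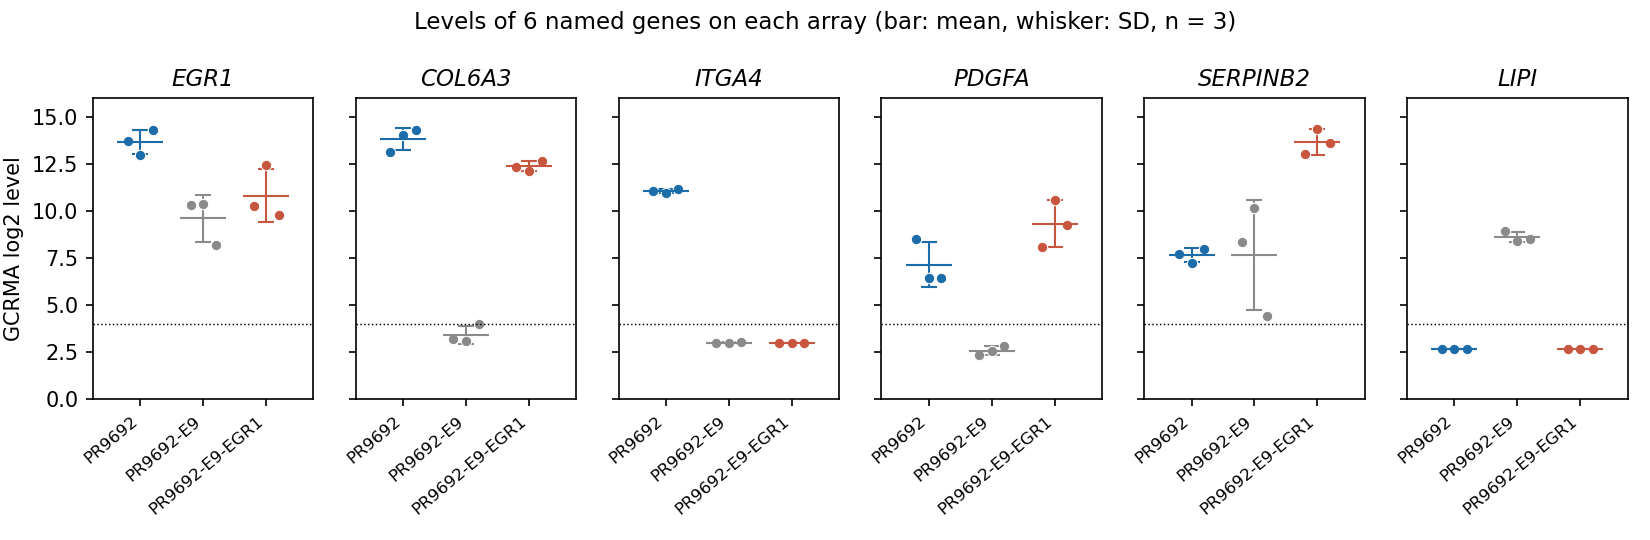
Log2 levels of 6 genes (EGR1, COL6A3, ITGA4, PDGFA, SERPINB2 and LIPI) in the 3 lines, with each point 1 array, each bar the mean of 3 arrays, each whisker the SD and the dotted line at log2 4. EGR1 averaged 13.67 in PR9692, 9.62 in PR9692-E9 and 10.82 in PR9692-E9-EGR1, while ITGA4 stood above the dotted line in PR9692 alone.

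The first comparison asked how the metastatic parent differed from its non-metastatic clone. Several collagen genes were higher in PR9692, but not all. Outside the rule, COL3A1 (0.61, adjusted p = 0.617) and COL12A1 (-1.07, adjusted p = 0.432) were not called. COL6A3, a chain of collagen VI, read 13.83 ± 0.59 (log2, SD, n = 3) in PR9692 and stayed under log2 4 on all 3 PR9692-E9 arrays (3.41 ± 0.49), a difference of at least 9.83 or 909.6-fold (adjusted p = 7.6e-07). ITGA4, the alpha 4 integrin subunit that binds fibronectin and VCAM1, read 11.07 ± 0.12 in PR9692 and was also under 4 throughout PR9692-E9 (at least 7.07 higher, adjusted p = 2.7e-08). In the other direction CACNA2D1, an auxiliary subunit of voltage-gated calcium channels, read 8.82 ± 0.93 in PR9692-E9 and was at least 4.82 lower in PR9692 (adjusted p = 3.9e-05). LIPI, a lipase, was at least 4.62 lower (adjusted p = 5.1e-07). COL6A3, COL6A1 and ITGA4 lie on chromosome 7, of whose 272 genes tested 54 rose and 1 fell, with a median difference of 0.32.

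Other genes higher in PR9692 were under log2 4 throughout PR9692-E9. These included COL5A1, a collagen V chain (at least 7.54 higher, adjusted p = 5.0e-05), GFPT2, an enzyme of hexosamine synthesis (at least 6.70, adjusted p = 6.9e-08), COL6A2 (at least 6.40, adjusted p = 0.000203), MSRB3, a methionine sulfoxide reductase (at least 6.07, adjusted p = 1.3e-06), RARRES2, the chemoattractant chemerin (at least 64.0-fold, adjusted p = 1.0e-05), and COL1A2, a collagen I chain (at least 5.66, adjusted p = 0.00221). COL1A2 varied between the PR9692 arrays (SD 2.46), and 1 of its 2 probe sets was called. COL6A1 rose by at least 7.14 (adjusted p = 0.00154) and ANXA7, a calcium-dependent membrane-binding annexin, by 7.01 ± 0.31 (SE, adjusted p = 4.2e-06). Among the genes lower in PR9692, KRT75, a keratin, changed by -5.63 ± 0.60 (adjusted p = 0.000628), FABP1, a fatty acid carrier, by -5.18 ± 0.84 (adjusted p = 0.00613) and EYA2, a transcriptional coactivator and phosphatase, by -5.07 ± 0.31 (adjusted p = 2.5e-05). PTGFRN was at least 4.43 lower, NMU, the peptide neuromedin U, at least 3.84, UMOD, uromodulin, at least 3.69, IRX1, a homeobox factor, at least 3.47 and SLITRK6, a transmembrane protein of neurons, at least 3.31.

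Lists of matrix, attachment and motility genes were called higher in PR9692 at the preset correlation, but none was with an estimated correlation. Another split of the same 6 arrays also called 6 lists. Of 28 extracellular matrix genes tested, 13 rose and 1 fell (15 and 2 adjusted over the list alone), with camera adjusted p = 8.5e-07 and adjusted p = 0.218 with an estimated correlation. Those that rose included COL6A3, COL5A1, COL6A2, COL6A1 and COL1A2, and THBS1, a thrombospondin, was the member that fell (-2.20 ± 0.41, adjusted p = 0.0124, and 0.0568 without PR9692 replicate 2). Of 24 integrins and cadherins 7 rose and none fell (8 and 1 adjusted over the list alone; adjusted p = 0.000384, and adjusted p = 0.0847 with an estimated correlation). ITGB5, an integrin beta subunit, rose by 3.25 ± 0.39 (adjusted p = 0.00128), and ALCAM, an adhesion molecule of the immunoglobulin family, by at least 0.96 (adjusted p = 0.000400). This count was 4 without PR9692 replicate 2 and 3 without PR9692 replicate 3. Of 41 genes of the actin cytoskeleton and motility, 4 rose and none fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.00127, and adjusted p = 0.218 with an estimated correlation). The called share of this list was near the 10.1% of all probe sets tested. MYL9, a myosin regulatory light chain, rose by 5.07 ± 0.33 (adjusted p = 3.9e-05), S100A11, a calcium-binding protein, by 1.41 ± 0.24 (adjusted p = 0.00759), and FSCN1, the actin-bundling protein fascin, by at least 1.82 (adjusted p = 1.1e-05). Without PR9692-E9 replicate 3, the array that stood apart, these 3 lists were still called (adjusted p = 1.9e-05, 0.000360 and 0.0235).

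Another 3 lists were called on all arrays but not without PR9692-E9 replicate 3. Of 16 MAPK feedback regulators 3 rose (3 adjusted over the list alone; adjusted p = 0.0248, and adjusted p = 0.218 with an estimated correlation). They included SPRY2, an inhibitor of receptor tyrosine kinase signalling (1.45 ± 0.25, adjusted p = 0.00845), and DUSP6, an ERK phosphatase (1.65 ± 0.31, adjusted p = 0.0121, and 0.0529 without PR9692 replicate 3). Without PR9692 replicate 3 the count was 1, and without PR9692-E9 replicate 3 the list had adjusted p = 0.0817. Of 22 genes of unfolded protein and amino acid stress 3 rose (3 adjusted over the list alone; adjusted p = 0.0229, and adjusted p = 0.218 with an estimated correlation). They included TRIB2, a pseudokinase that is not itself a chaperone (1.66 ± 0.32, adjusted p = 0.0135). That count was 1 without PR9692-E9 replicate 1 or PR9692-E9-EGR1 replicate 3 and 5 without PR9692-E9 replicate 3, when the list had adjusted p = 0.0730. Of 3 neural and glial markers tested, SYT1, a synaptic vesicle calcium sensor, rose by at least 2.72 (adjusted p = 8.7e-05). The list had adjusted p = 0.0248, adjusted p = 0.218 with an estimated correlation, 0.0870 without PR9692-E9 replicate 3, 0.265 with no filter on level and 0.0563 with the mean over each gene's probe sets.

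No other list was called by camera in this comparison. Of 33 growth factors and receptors 4 rose and 3 fell (5 and 4 adjusted over the list alone; adjusted p = 0.662). The ligands PDGFD and PDGFA rose by at least 4.07 and 3.14 (adjusted p = 0.000684 and 0.00439; 1 of the 2 PDGFA probe sets was called), and BAMBI, a decoy receptor of the TGF-beta family, rose by 2.91 ± 0.27 (adjusted p = 0.000312). The number that fell was 1 without PR9692 replicate 1, 2 or 3, PR9692-E9 replicate 2 or PR9692-E9-EGR1 replicate 3, and 6 without PR9692-E9 replicate 3. Of 17 described EGR1 targets 3 rose and 2 fell (4 and 5 adjusted over the list alone; adjusted p = 0.890), among them PDGFA and the death receptor FAS, which rose by 1.95 ± 0.27 (adjusted p = 0.00251). Without PR9692-E9 replicate 3, 5 rose; 1 fell without PR9692 replicate 1 or 3, PR9692-E9 replicate 1 or PR9692-E9-EGR1 replicate 3, and 0 without PR9692 replicate 2. Of 17 cytokine, chemokine and prostaglandin genes 3 rose (3 adjusted over the list alone, and no call by camera). TNFAIP2 rose by 6.07 ± 0.72 (adjusted p = 0.00113) and TNFAIP6, a hyaluronan-binding protein, by 2.69 ± 0.35 (adjusted p = 0.00201). Of 20 matrix proteases and inhibitors 2 rose and 2 fell (3 and 3 adjusted over the list alone; adjusted p = 0.890). TIMP2, a metalloproteinase inhibitor, rose by 1.49 ± 0.21 (adjusted p = 0.00321) and CTSD, the lysosomal protease cathepsin D, changed by -2.14 ± 0.26 (adjusted p = 0.00147). Each of these 2 protease counts was 1 without PR9692 replicate 2 or 3 or PR9692-E9 replicate 1 or 2, and the number that fell was also 1 without any single PR9692-E9-EGR1 array.

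The transcription factor and marker lists held few calls. Of 11 regulators of epithelial-mesenchymal transition 3 rose (4 adjusted over the list alone; adjusted p = 0.0661), among them TWIST1, a helix-loop-helix factor (2.39 ± 0.48, adjusted p = 0.0172). None of them was called without PR9692 replicate 1, 2 or 3, when TWIST1 had adjusted p between 0.0512 and 0.0581, and 1 was called without PR9692-E9 replicate 1 or 2. Of 17 HOX and limb position genes 3 rose (4 adjusted over the list alone; adjusted p = 0.890), with HOXA11 at 2.10 ± 0.32 (adjusted p = 0.00439) and 1 call left without PR9692 replicate 2 or PR9692-E9-EGR1 replicate 3. Of 5 epithelial markers 2 fell (2 adjusted over the list alone; adjusted p = 0.348), the keratin KRT7 by at least 2.66 (adjusted p = 0.00602) and the laminin chain LAMA3 with -1.40 ± 0.23 (adjusted p = 0.00592). Of 13 immediate early genes CCN2, a secreted matricellular protein, was the only call (2.95 ± 0.75, adjusted p = 0.0413; 4 rose and 1 fell adjusted over the list alone; list adjusted p = 0.270), and its call was lost in 8 of the 9 fits that left out 1 array, all but that without PR9692-E9 replicate 2, with adjusted p between 0.0595 and 0.124. In this list 3 rose without PR9692-E9 replicate 3, and 1 fell without PR9692 replicate 1. Among 4 endothelial markers the ETS factor FLI1 rose by 2.14 ± 0.45 (adjusted p = 0.0194, but 0.0775 and 0.0738 without PR9692 replicates 2 and 3; list adjusted p = 0.352). Of 28 hypoxia and glycolysis genes, 14 Wnt and Notch genes and 25 interferon response genes, 1 rose and 1 fell in each (1 and 1, 2 and 1, and 2 and 3 adjusted over the list alone; adjusted p = 0.890, 0.213 and 0.207), and with 1 array left out these counts ranged from 0 to 3.

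None of the 46 cell cycle genes, 22 cholesterol and lipid synthesis genes, 5 haematopoietic markers, 4 cartilage and bone markers or the 1 skeletal muscle marker tested passed limma's test. Unadjusted p lay under 0.05 for 6 of the cell cycle genes, 5 of the cholesterol genes, 2 haematopoietic markers, 0 cartilage and bone markers and the muscle marker, which alone passed when adjusted over the list alone. The lists had adjusted p = 0.352, 0.352, 0.662, 0.948 and 0.350. Without PR9692-E9 replicate 3, 2 cell cycle genes rose and 4 fell. Median, mean and test differed in sign for 5 lists that were not called. These were the cytokines (median -0.04, mean 0.50, test up), the HOX genes (-0.06, 0.05, up), the hypoxia genes (-0.04, 0.08, down), the epithelial markers (0.06, -0.85, down) and the haematopoietic markers (-0.02, 0.20, up).

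Over all probe sets, 1038 were higher and 651 lower in PR9692, 1689 of 16727 tested (10.1%), and 1231 of them differed at least 2-fold. The total was 857 without PR9692 replicate 2, 845 without PR9692 replicate 3, 1070 without PR9692-E9 replicate 1, 1058 without PR9692-E9 replicate 2 and 3618 without PR9692-E9 replicate 3. The share of calls that were higher in PR9692, 61.5%, was 49.0% without that last array and 42.7% with array weights, when 9025 probe sets passed. With no filter on level the calls of TRIB2, THBS1, TWIST1, CCN2 and FLI1 were lost, and all of these but TRIB2 were also lost when the 6 arrays compared were fitted alone, when the total was 1019.

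**Figure D2:**
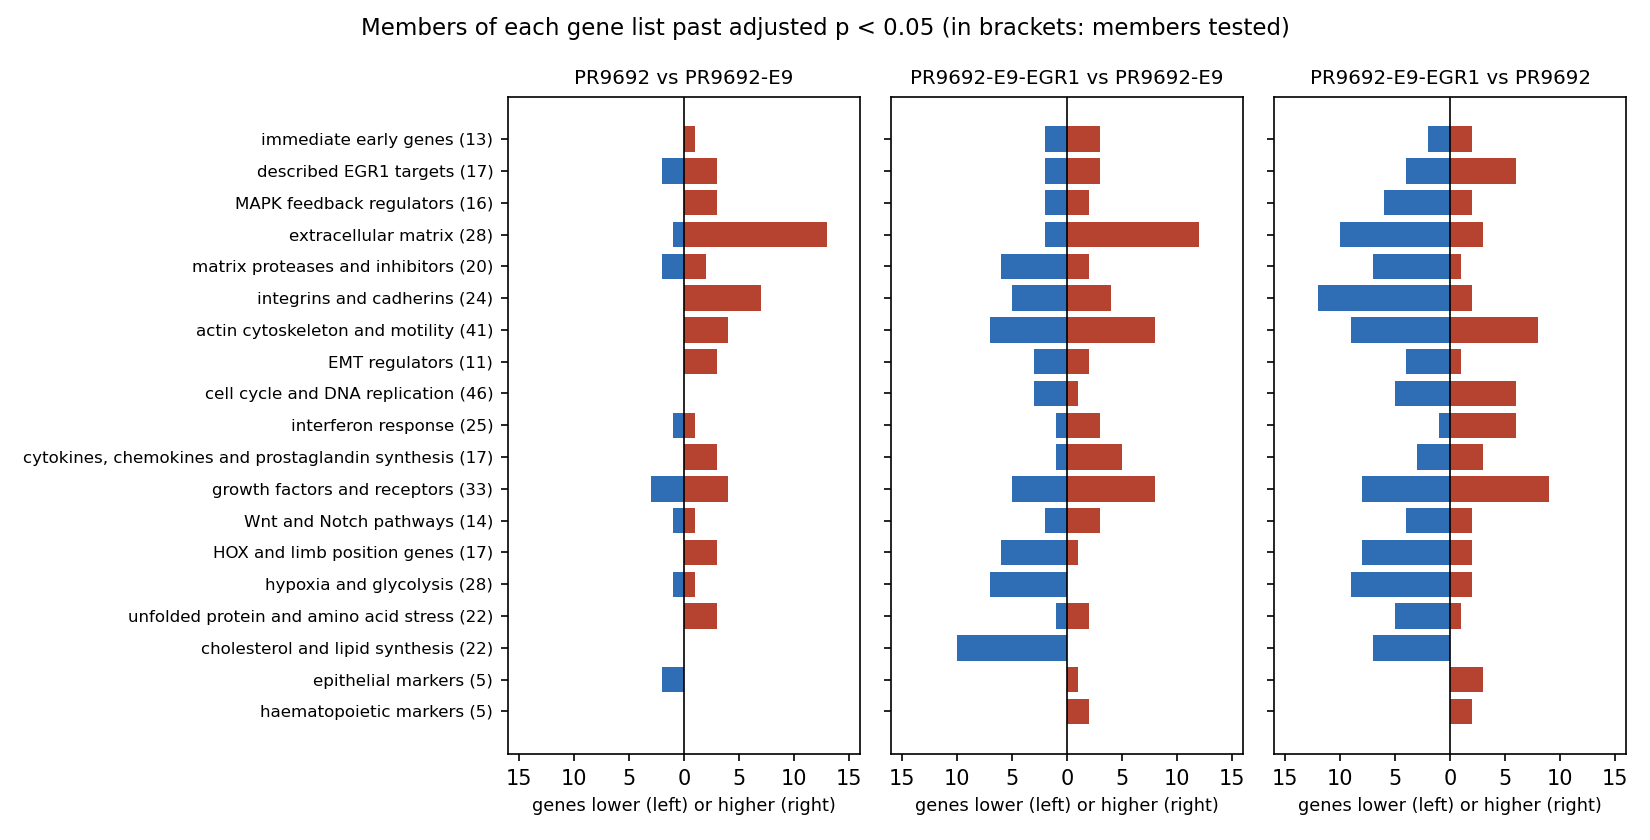
Members of the 19 gene lists with at least 5 genes tested that were lower (bars to the left) or higher (bars to the right) at adjusted p under 0.05, with 1 panel per comparison and the number of genes on the horizontal axis. In PR9692 against PR9692-E9, 13 extracellular matrix genes were higher and 1 was lower.

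The second comparison asked what distinguished the clone carrying the EGR1 vector from the clone itself. RBM24, an RNA-binding regulator of splicing, read 13.29 ± 0.22 (log2, SD, n = 3) in PR9692-E9-EGR1 and was under log2 4 in PR9692-E9, a difference of at least 9.29 (adjusted p = 9.4e-08). COL6A3 was at least 8.38 higher (12.38 ± 0.27, adjusted p = 2.1e-06), and PDGFA, a platelet-derived growth factor chain and a described EGR1 target, at least 5.32 higher (9.32 ± 1.24, adjusted p = 0.000481). HINTW, a gene of the female-specific W chromosome, read 13.33 ± 0.48 in PR9692-E9 and was at least 9.33 lower in PR9692-E9-EGR1 (adjusted p = 1.3e-07), where 20 of 27 W-linked probe sets tested were not under 4 throughout.

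Of the other genes that rose, LRRN4 rose by at least 6.66 (adjusted p = 1.8e-05), MSRB3 by at least 5.46 (adjusted p = 2.2e-06) and CERS6, a ceramide synthase, by at least 4.93 (adjusted p = 6.4e-06). MYL9 rose by 6.30 ± 0.33 (adjusted p = 1.4e-05), ANXA7 by 6.29 ± 0.31 (adjusted p = 9.0e-06), COL6A1 by at least 6.11 (adjusted p = 0.00211) and INHBA, the activin A subunit, by 6.05 (adjusted p = 0.00770). The genes that fell included CALML4, a calmodulin-like protein (at least 5.62), TMEM26 (at least 5.54), CACNA2D1 (at least 4.82), NKX2-1, a homeobox factor of thyroid and lung (at least 4.66), LIPI (at least 4.62) and UBE2R2L (at least 3.35), with adjusted p between 3.9e-07 and 0.000238. KLF15, a Krüppel-like factor, changed by -6.31 ± 0.70 (adjusted p = 0.000659) and RASGRP3, a Ras exchange factor, by -5.47 ± 0.76 (adjusted p = 0.00175).

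Of 22 cholesterol and lipid synthesis genes 10 fell and none rose (11 and 0 adjusted over the list alone; adjusted p = 0.000431, and adjusted p = 0.600 with an estimated correlation). SC5D, a sterol desaturase, changed by -2.23 ± 0.33 (adjusted p = 0.00252), INSIG1, a regulator of sterol sensing, by -1.91 ± 0.58 (adjusted p = 0.0428) and ACLY, which makes cytosolic acetyl-CoA, by -1.08 ± 0.32 (adjusted p = 0.0379). SCD, a fatty acid desaturase, was at least 1.85 lower (adjusted p = 0.0254). Of these SC5D kept its call whichever array was left out; SCD lost it without PR9692-E9 replicate 1 (adjusted p = 0.0755) or 3 (0.0612) or PR9692-E9-EGR1 replicate 2 (0.0862) or 3 (0.0724). The number that fell was 5 without PR9692 replicate 2, 3 without PR9692-E9 replicate 1, 6 without PR9692-E9 replicate 3, and 3 without PR9692-E9-EGR1 replicate 2 or 3. INSIG1 lost its call without PR9692 replicate 2, PR9692-E9 replicate 1 or 3 or PR9692-E9-EGR1 replicate 2 or 3 (adjusted p between 0.0658 and 0.140). ACLY lost it without PR9692 replicate 2 or 3, PR9692-E9 replicate 1 or PR9692-E9-EGR1 replicate 2 or 3 (adjusted p between 0.0541 and 0.124). SCD, INSIG1 and ACLY were also not called when the 6 arrays compared were fitted alone.

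Of 28 extracellular matrix genes 12 rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 0.00365, and adjusted p = 0.595 with an estimated correlation). COL6A3 and COL6A1 were joined by COL6A2 (at least 3.30 higher, adjusted p = 0.00182) and CCN2 (4.94 ± 0.75, adjusted p = 0.00262), and 1 member fell without PR9692-E9 replicate 1 or PR9692-E9-EGR1 replicate 2. Without PR9692-E9 replicate 3, the array that stood apart, the cholesterol and matrix lists were still called (adjusted p = 0.000697 and 0.000983). Poly-A control transcripts, added to the RNA before labelling, were lower on all 3 PR9692-E9-EGR1 arrays than on the other 6 in 18 of 18 detected probe sets, by a median of -2.79 on the log2 scale, and these arrays were those in which the cholesterol genes lay lower and the matrix genes higher. Hybridization controls, added after labelling, differed by a median of -0.04 over their 18 probe sets, but the median level of these controls was also apart, at 10.24 to 10.39 on the PR9692-E9-EGR1 arrays and 9.64 to 10.07 on the others.

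Adhesion, cytoskeleton and protease genes moved in both directions. So did all probe sets tested, of which 26.0% were called, 2227 higher and 2115 lower. Of 24 integrins and cadherins 4 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.914). ITGB3, an integrin beta subunit, was at least 2.59 higher (adjusted p = 2.4e-05) and GPC1, a glypican, at least 2.39 lower (adjusted p = 0.000656). Of 41 actin and motility genes 8 rose and 7 fell (9 and 7 adjusted over the list alone; adjusted p = 0.456), or 5 and 4 without PR9692-E9-EGR1 replicate 3. TPM1, a tropomyosin, rose by 1.63 ± 0.21 (adjusted p = 0.00121), CNN2, a calponin, rose by 1.98 ± 0.28 (adjusted p = 0.00203), and CALD1, the actin-binding caldesmon, changed by -3.47 ± 0.64 (adjusted p = 0.00627). Of 20 proteases and inhibitors 2 rose and 6 fell (2 and 8 adjusted over the list alone; adjusted p = 0.160). SERPINB2, a plasminogen activator inhibitor, rose by 6.02 ± 1.20 (adjusted p = 0.00854) from a level that varied between PR9692-E9 arrays (7.65 ± 2.93, SD, n = 3), whereas CTSD changed by -3.37 ± 0.26 (adjusted p = 0.000115) and FAP, a stromal serine protease, by -1.99 ± 0.32 (adjusted p = 0.00336). The number that fell was 3 without PR9692-E9 replicate 1, and 1 rose without PR9692-E9-EGR1 replicate 3. Of 11 regulators of epithelial-mesenchymal transition 2 rose and 3 fell (2 and 3 adjusted over the list alone; adjusted p = 0.914). TWIST2 changed by -2.72 ± 0.33 (adjusted p = 0.00102) and HMGA2, a chromatin protein, by 1.91 ± 0.40 (adjusted p = 0.0102).

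Signalling genes also moved both ways, as did the 26.0% of all probe sets that were called in this comparison. Of 17 described EGR1 targets 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.502), with PDGFA higher and TGFB1, a transforming growth factor, lower (-2.79 ± 0.37, adjusted p = 0.00151). Without PR9692-E9-EGR1 replicate 2, 1 rose and 1 fell, and 1 fell without PR9692-E9-EGR1 replicate 3. Of 13 immediate early genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; adjusted p = 0.563). CCN2 rose, and JUN, a subunit of AP-1, changed by -1.91 ± 0.36 (adjusted p = 0.00716). Of 16 MAPK feedback regulators 2 rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.910). IL17RD, an inhibitor of FGF signalling, was at least 2.59 higher (adjusted p = 4.6e-05), and ETV5, an ETS factor, changed by -1.67 ± 0.16 (adjusted p = 0.000384). Without PR9692-E9-EGR1 replicate 2, 1 rose. Of 33 growth factors and receptors 8 rose and 5 fell (9 and 5 adjusted over the list alone; adjusted p = 0.288). BAMBI rose by 5.38 ± 0.27 (adjusted p = 1.1e-05), and IGFBP5, an insulin-like growth factor binding protein, changed by -2.31 ± 0.41 (adjusted p = 0.00508). These counts were 5 and 3 without PR9692-E9-EGR1 replicate 2 and 4 and 2 without replicate 3, and 3 fell without PR9692 replicate 3 or PR9692-E9 replicate 1 or 3. Of 17 cytokine, chemokine and prostaglandin genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0967, and 0.0282 without PR9692-E9 replicate 3). LIF, an interleukin 6 family cytokine, rose by 2.21 ± 0.31 (adjusted p = 0.00180). Without PR9692-E9-EGR1 replicate 2 or 3, 3 rose. Of 14 Wnt and Notch genes 3 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.563). The ligand WNT5B rose by 3.12 ± 0.53 (adjusted p = 0.00436) and the Notch-modifying LFNG by 2.37 ± 0.27 (adjusted p = 0.000702). Without PR9692-E9 replicate 1 or PR9692-E9-EGR1 replicate 1 or 3, 1 fell.

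Of 28 hypoxia and glycolysis genes 7 fell and none rose (7 and 1 adjusted over the list alone; adjusted p = 0.137), among them ENO2, an enolase (-2.53 ± 0.46, adjusted p = 0.00609). Without PR9692-E9-EGR1 replicate 2, 4 fell. Of 17 HOX and limb position genes 6 fell and 1 rose (10 and 3 adjusted over the list alone; adjusted p = 0.137). HOXA4 changed by -1.58 ± 0.28 (adjusted p = 0.00526) and MSX2 by -1.68 ± 0.34 (adjusted p = 0.00975). Between 0 and 1 rose with 1 array left out, and 3 fell without PR9692-E9 replicate 1 or PR9692-E9-EGR1 replicate 2 or 3. Of 46 cell cycle genes 1 rose and 3 fell (0 and 1 adjusted over the list alone; adjusted p = 0.563), among them the kinase inhibitor CDKN2B (-3.44 ± 0.34, adjusted p = 0.000384). Without PR9692-E9-EGR1 replicate 1, 10 fell, and 1 without replicate 2 or 3. Of 25 interferon response genes 3 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.502), with TRIM25, a ubiquitin ligase, at 1.07 ± 0.16 (adjusted p = 0.00258). Without PR9692 replicate 1, 5 rose, and 1 without PR9692-E9 replicate 1 or PR9692-E9-EGR1 replicate 2 or 3. Of 22 stress genes 2 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.288), and with 1 array left out between 0 and 5 rose. Of 5 haematopoietic markers the leukocyte phosphatase PTPRC rose by at least 1.98 (adjusted p = 4.6e-05) and the ETS factor SPI1 by 2.82 ± 0.32 (adjusted p = 0.000718). The list had adjusted p = 0.0611, and 0.0282 without PR9692-E9 replicate 3. Of 3 neural and glial markers 2 fell (3 adjusted over the list alone; adjusted p = 0.0611), including ISL1, a LIM homeobox factor (-2.41 ± 0.35, adjusted p = 0.00227). Of the cartilage markers COL9A1, a collagen IX chain, rose by at least 2.84 (adjusted p = 1.8e-05; list adjusted p = 0.502). No endothelial or muscle marker passed limma's test, with an unadjusted p under 0.05 for 1 and 0 of them.

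Over all probe sets, 2227 were higher and 2115 lower in PR9692-E9-EGR1, 4342 of 16727 tested (26.0%), and 2900 of them differed at least 2-fold. The total was 2529 without PR9692-E9-EGR1 replicate 2, 2140 without PR9692-E9-EGR1 replicate 3, 2713 with no filter on level, when TNFAIP2, SCD, INSIG1 and ACLY lost their calls, and 11887 with array weights. Median, mean and test differed in sign for the integrins and cadherins (median 0.03, mean -0.08, test up) and the regulators of epithelial-mesenchymal transition (0.23, -0.06, down).

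The third comparison set the infected clone against the parent, both labelled metastatic. ITGA4, 11.07 ± 0.12 (log2, SD, n = 3) in PR9692, was under log2 4 in PR9692-E9-EGR1 as it was in PR9692-E9, a difference of at least 7.07 (adjusted p = 8.7e-09). GFPT2 and COL1A2 were likewise at least 6.70 and 5.66 lower than in PR9692 (adjusted p = 3.9e-08 and 0.00111). RBM24 was at least 9.29 higher in PR9692-E9-EGR1 (adjusted p = 5.0e-08), and SERPINB2 was 64.2-fold higher (13.67 ± 0.67 against 7.66 ± 0.38, adjusted p = 0.00630). HINTW, of the W chromosome, was at least 10.34 lower (adjusted p = 3.9e-08).

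Other genes that rose in PR9692-E9-EGR1 included KRT75 (5.71 ± 0.60, adjusted p = 0.000377), DIO3, which inactivates thyroid hormone (at least 5.06, adjusted p = 0.000232), FABP1 (5.21 ± 0.84, adjusted p = 0.00255), GK2, a glycerol kinase (4.98 ± 0.68, adjusted p = 0.00128), and RDH10, a retinol dehydrogenase (4.83 ± 0.45, adjusted p = 0.000211). KIAA1217, OVOA and FAM132A rose by at least 5.00, 4.62 and 3.20 (adjusted p = 1.4e-05, 7.9e-05 and 1.4e-05). CALML4 fell to under log2 4 by at least 5.82, TMEM26 by at least 5.63, MGAT3, a glycosyltransferase of N-glycans, by at least 5.55, KLHL42 by at least 4.89 and UBE2R2L by at least 4.77, with adjusted p between 7.4e-07 and 4.7e-05.

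Of 24 integrins and cadherins 12 were lower in PR9692-E9-EGR1 and 2 higher (13 and 2 adjusted over the list alone; adjusted p = 0.0259, and adjusted p = 0.193 with an estimated correlation). ITGB5 changed by -3.47 ± 0.39 (adjusted p = 0.000529), GPC1 was at least 2.40 lower (adjusted p = 0.000483) and ITGB3 at least 2.59 higher (adjusted p = 1.7e-05). Without PR9692 replicate 2 or 3 or PR9692-E9-EGR1 replicate 3, 1 member rose. The 3 neural and glial markers tested all fell (3 adjusted over the list alone; adjusted p = 0.0259, and adjusted p = 0.193 with an estimated correlation): SYT1 by at least 2.72 (adjusted p = 1.4e-05), ISL1 with -3.10 ± 0.35 (adjusted p = 0.000550) and TUBB3, a neuronal tubulin, with -1.40 ± 0.29 (adjusted p = 0.00681). With no filter on level both lists lost their calls (adjusted p = 0.0572 and 0.149), as did COL6A2. The poly-A controls, with a median difference of -2.79 on the PR9692-E9-EGR1 arrays, were lower on the same arrays as both lists.

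Of 28 extracellular matrix genes 3 rose and 10 fell (3 and 10 adjusted over the list alone; adjusted p = 0.351). COL5A1 changed by -4.95 ± 0.60 (adjusted p = 0.000729), COL6A2 by -3.11 ± 0.73 (adjusted p = 0.0120) and THBS1 by 4.05 ± 0.41 (adjusted p = 0.000337). Without PR9692 replicate 2 or 3 or PR9692-E9-EGR1 replicate 2 or 3, 1 member rose, and 5 without PR9692-E9 replicate 3. Of 20 proteases and inhibitors 1 rose and 7 fell (1 and 7 adjusted over the list alone; adjusted p = 0.137), SERPINB2 being the one that rose and FAP among those that fell (-3.52 ± 0.32, adjusted p = 0.000181). Of 41 actin and motility genes 8 rose and 9 fell (9 and 10 adjusted over the list alone; adjusted p = 0.376). CALD1 changed by -5.72 ± 0.64 (adjusted p = 0.000511) and VCL, vinculin, by 1.33 ± 0.23 (adjusted p = 0.00340). Without PR9692-E9-EGR1 replicates 2 and 3 in turn, 4 and 5 rose. Of 11 regulators of epithelial-mesenchymal transition 1 rose and 4 fell (1 and 4 adjusted over the list alone; adjusted p = 0.329). TWIST2 changed by -4.29 ± 0.33 (adjusted p = 8.1e-05) and PRRX1 by -1.66 ± 0.26 (adjusted p = 0.00228). Without PR9692 replicate 2 or 3 or PR9692-E9-EGR1 replicate 1 or 3, 0 rose. Of 22 cholesterol and lipid synthesis genes 7 fell (7 adjusted over the list alone; adjusted p = 0.0525). SC5D changed by -2.48 ± 0.33 (adjusted p = 0.00117) and SREBF2, a sterol-regulated transcription factor, by -1.71 ± 0.21 (adjusted p = 0.000709). Of 28 hypoxia and glycolysis genes 2 rose and 9 fell (2 and 9 adjusted over the list alone; adjusted p = 0.329). NDRG1 changed by -3.72 ± 0.53 (adjusted p = 0.00146) and PFKL, a phosphofructokinase, by -1.71 ± 0.22 (adjusted p = 0.00100). Without PR9692 replicate 2, 5 fell, and between 0 and 4 rose with 1 array left out.

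Of 17 described EGR1 targets 6 rose and 4 fell (7 and 4 adjusted over the list alone; adjusted p = 0.528). THBS1 was among those that rose, and FAS changed by -2.17 ± 0.27 (adjusted p = 0.000752). Either 2 or 3 rose without any one of PR9692 replicates 1, 2 and 3, PR9692-E9 replicates 1 and 2 and PR9692-E9-EGR1 replicates 2 and 3. Of 16 MAPK feedback regulators 2 rose and 6 fell (2 and 6 adjusted over the list alone; adjusted p = 0.323), including ETV5 (-2.46 ± 0.16, adjusted p = 3.7e-05). Without PR9692 replicate 2 or 3 or PR9692-E9-EGR1 replicate 2, 1 rose. Of 33 growth factors and receptors 9 rose and 8 fell (10 and 8 adjusted over the list alone; adjusted p = 0.528). PDGFD was at least 4.07 lower (adjusted p = 0.000438), and ID2, an inhibitor of helix-loop-helix factors, changed by 3.06 ± 0.41 (adjusted p = 0.00111). Of 17 HOX and limb position genes 2 rose and 8 fell (2 and 8 adjusted over the list alone; adjusted p = 0.137), including HOXA6 (-2.44 ± 0.30, adjusted p = 0.000752). Without any 1 of PR9692 replicates 1, 2 and 3 and PR9692-E9-EGR1 replicates 2 and 3, 4 or 5 fell. Of 25 interferon response genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.129), with the antiviral GTPase MX1 at 3.34 ± 0.36 (adjusted p = 0.000454). Without PR9692-E9-EGR1 replicate 2 or 3, 3 rose. Of 5 epithelial markers 3 rose (3 adjusted over the list alone; adjusted p = 0.0725). KRT7 rose by at least 3.23 (adjusted p = 0.00144) and LAMA3 by 1.38 ± 0.23 (adjusted p = 0.00273). Of 46 cell cycle genes 6 rose and 5 fell (5 and 5 adjusted over the list alone; adjusted p = 0.790). CDKN2B changed by -4.35 ± 0.34 (adjusted p = 7.9e-05) and cyclin CCNE2 by 2.95 ± 0.55 (adjusted p = 0.00467). With 1 array left out, between 1 and 12 rose and between 2 and 9 fell.

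Over all probe sets, 2915 were higher and 2833 lower in PR9692-E9-EGR1 than in PR9692, 5748 of 16727 tested (34.4%), and 3928 of them differed at least 2-fold. The total was 3829 without PR9692 replicate 2, 3829 without PR9692 replicate 3, 3668 without PR9692-E9-EGR1 replicate 3 and 10810 with array weights. Median, mean and test differed in sign for the immediate early genes (median 0.23, mean 0.00, test down) and the Wnt and Notch genes (0.01, -0.09, down).

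The last comparison asked which genes changed the same way in both metastatic lines against PR9692-E9. COL6A3, COL6A1, COL6A2, MSRB3, ANXA7, MYL9, PDGFA, TNFAIP2 and BAMBI rose in both lines, and LIPI, CACNA2D1 and CTSD fell in both. All 3 collagen VI chains measured were thus higher in both. BAMBI rose by 2.91 ± 0.27 in PR9692 and 5.38 ± 0.27 in PR9692-E9-EGR1, and CTSD changed by -2.14 ± 0.26 and -3.37 ± 0.26. THBS1 went opposite ways, with -2.20 ± 0.41 in PR9692 and 1.85 ± 0.41 in PR9692-E9-EGR1 (adjusted p = 0.0124 and 0.0140, but 0.0568 without PR9692 replicate 2 and 0.0505 without PR9692-E9-EGR1 replicate 2), and neither call held with no filter on level.

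Of the 1689 probe sets changed in PR9692, 622 (36.8%) changed the same way in PR9692-E9-EGR1, 341 higher and 281 lower, 147 changed the opposite way and 920 were not called there. Independent lists of these sizes would share 138.2 higher and 82.3 lower and go opposite ways in 217.9. Simulated unchanged groups set against shared controls shared 3.42 on average and 21 at most in 100 simulations. Those simulations held no changed probe sets, and their noise was independent between probe sets. They therefore cover neither lines that truly differ nor a control array that deviates across many probe sets, and cannot tell how much of the 622 such an array gives. The correlation of the log2 differences across probe sets, which are not independent replicates, was 0.295 against 0.707 in those simulations, and their covariance was 0.263 against 0.115, a difference of 0.148. The 3 PR9692-E9 arrays are too few to split, so part of the excess may come from the shared controls. The 622 became 359 without PR9692 replicate 2, 350 without PR9692 replicate 3, 366 without PR9692-E9-EGR1 replicate 3, 996 without PR9692-E9 replicate 3 and 3904 with array weights.

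**Figure D3:**
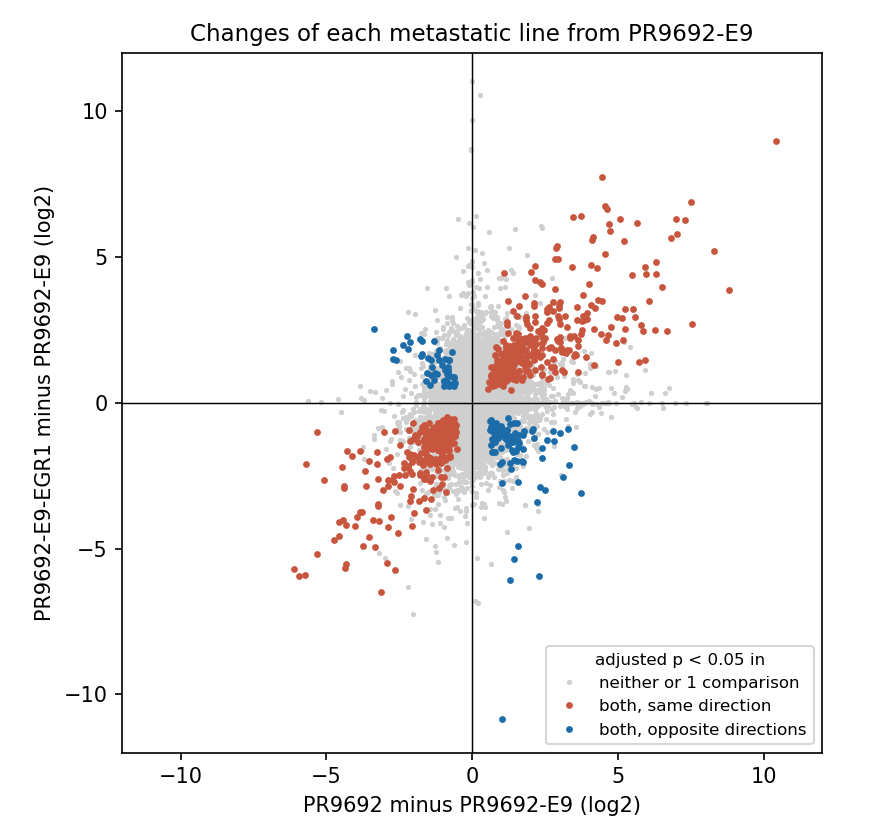
Log2 difference from PR9692-E9 of each of 16727 probe sets in PR9692 (horizontal axis) and in PR9692-E9-EGR1 (vertical axis), with red points for the 622 called in both in the same direction, blue points for the 147 called in opposite directions and grey points for the rest. Across all points the correlation was 0.295, part of which comes from the control arrays that both axes share.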

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

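The tests of the number of changed probe sets weighed here were chosen only after the result was seen; the levels of the added controls and of the probe sets for other sequences are measurements outside the comparisons.

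Control transcripts with poly-A tails are added to RNA before it is labelled, and no comparison uses them. Of 24 such probe sets, 18 had a mean of log2 4 or more, and in 18 of 18 of these the 3 PR9692-E9-EGR1 arrays lay below all 6 others, with a median difference of -2.79 and a range of -4.86 to -1.71. PR9692 and PR9692-E9 differed by a median of -0.03 on the same controls, and the hybridization controls added after labelling differed by a median of -0.04 over 18 probe sets between PR9692-E9-EGR1 and the others. Their median level on each array was nevertheless higher on the 3 PR9692-E9-EGR1 arrays (10.24 to 10.39) than on the other 6 (9.64 to 10.07). The labels give no labelling run, so a run and the PR9692-E9-EGR1 group cannot be told apart.

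The array holds 744 probe sets named for sequences other than known chicken genes, and a signal appeared in 4 of them in PR9692-E9-EGR1 alone. Their mean levels there were 10.08 ± 0.43, 11.83 ± 0.22, 12.95 ± 0.67 and 8.14 ± 0.56 (log2, SD, n = 3), while their means in PR9692 and PR9692-E9 were 3.79 at most. Another 3 of the 744 reached a mean of 4 in any group. The sources used here do not say what sequence the vector carries besides EGR1, so these probe sets were not assigned to it.

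More probe sets changed between PR9692-E9-EGR1 and PR9692-E9 than between PR9692 and PR9692-E9, 4342 against 1689, a ratio of 2.57. Without PR9692-E9 replicate 3 the ratio was 1.16, so that array may account for most of the gap. The labelling run remains open, with the poly-A difference of -2.79, because it is shared by the whole group. The EGR1 vector also remains open, because no empty-vector line was analysed here and the described EGR1 targets moved both ways (camera adjusted p = 0.502). Changes between the clone and its infected line that are unrelated to the vector remain open too, since only a single infected line was analysed. Without PR9692-E9 replicate 3, 1641 of the 1689 probe sets were called in the same direction and 0 in the opposite one.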

How the results depend on the processing

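The fit without PR9692-E9 replicate 3 and PR9692 replicate 1 was chosen after seeing the data, and the other alternatives were planned. No filter on level left 2713 changed probe sets in PR9692-E9-EGR1 against PR9692-E9, 413 changed the same way in both lines, and EGR1 at 4.05 (adjusted p = 0.0767) and -2.84 (adjusted p = 0.106); the cause was not tested. In PR9692-E9-EGR1 against PR9692 both lists then lost their calls and 1 other was called, that of cholesterol and lipid synthesis. Fitting only the arrays of both lines compared gave 1019, 3045 and 7035 in the 3 comparisons and 385 in common; the cause was not tested. An adjusted p under 0.01, stricter by construction, gave 678, 1757 and 2841 in the 3 comparisons and 225 in common. Array weights gave 9025, 11887, 10810 and 3904; the weights ran from 0.112 (PR9692-E9 replicate 3) to 21.1 (PR9692-E9 replicate 1) and their fit did not fully converge. With them the other EGR1 probe set turned from 0.48 to -1.18 in PR9692-E9-EGR1 against PR9692-E9 (adjusted p = 0.0150) and the main one to -0.30 (adjusted p = 0.457); the cause was not tested. Leaving out the 2 arrays named above gave 3826 in PR9692 against PR9692-E9, 1099 in common and 3 lists; the cause was not tested. An estimated correlation left 0, 0 and 0 lists of 6, 2 and 2. A block for replicate number gave 1231, 3643, 5184 and 460, and 7, 3 and 3 lists; the numbers do not pair samples, since 3 of 9 arrays correlated best with their own number.

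Leaving out 1 array at a time gave 845 to 3618, 2140 to 4457 and 3668 to 7510 changed probe sets, 350 to 996 in common, 3 to 9, 2 to 4 and 2 to 4 lists, and EGR1 differences of 3.33 to 4.42 for PR9692 against PR9692-E9, 0.39 to 1.72 for PR9692-E9-EGR1 against PR9692-E9 and -3.66 to -2.33 for PR9692-E9-EGR1 against PR9692. The stricter filter, centring, another quantile normalization and the trend and robust options kept all 4 counts within 1.5 times of those reported, but centring moved the share higher in PR9692 from 61.5% to 55.8%. Of 243 calls of named genes, 176 held with no filter, 224 of 224 with the stricter filter, 240 after centring, 241 after quantile normalization, 229 with the block, 208 with only the arrays compared, 237 with gene means and 194 to 234 without 1 array, and none changed direction under any alternative. Of 38439 probe sets, 16727 rose above the filter of log2 4, so genes below it were not tested and differences from it are bounds.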

Other observations

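The tests of the W chromosome and of chromosomes 5, 7, 15 and 18 were chosen only after the result was seen; the counts over other splits of the arrays were planned.

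A few genes behaved like switches between the lines; those outside the naming rule were chosen after their values were seen. At 7 or more on all PR9692 arrays and under 4 on all PR9692-E9 arrays there were 44 probe sets. Of these 18 were also under 4 on all PR9692-E9-EGR1 arrays, among them ITGA4, GFPT2, MGAT3 and, outside the rule, the collagen-binding integrin subunit ITGA11, with a mean of 9.22 in PR9692. Another 8 were at 7 or more on all PR9692-E9-EGR1 arrays, namely COL6A3, COL6A1, MSRB3, RARRES2, LRRN4 and, outside the rule, TFPI2, an inhibitor of serine proteases (7.90, 2.70 and 8.24 in PR9692, PR9692-E9 and PR9692-E9-EGR1), CFAP36 (9.80, 3.49 and 8.33) and CMTM7 (7.63, 2.88 and 8.78). The reverse, bright in PR9692-E9 and under 4 in PR9692, held for 8 probe sets, of which 4 were under 4 and 1 at 7 or more on all PR9692-E9-EGR1 arrays.

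Further genes that fell in both metastatic lines, outside the rule and chosen after their values were seen, included CADM1, a cell adhesion molecule (7.65 in PR9692-E9, at most 3.64 in the other lines' means), AQP9, an aquaporin (6.75 in PR9692-E9), and SELENOP1, a secreted selenoprotein, with differences of -3.34 (adjusted p = 0.00157) in PR9692 and -4.95 (adjusted p = 0.000161) in PR9692-E9-EGR1.

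Part of the transcripts of the W chromosome, which in birds is carried by females, were at the floor in PR9692-E9-EGR1. Of 27 W-linked probe sets tested, 7 were under 4 on all PR9692-E9-EGR1 arrays. They were of the 4 genes HINTW, UBE2R2L and, chosen after their values were seen, LOC430910 and UBAP2L2. These 7 were lower in PR9692-E9 than in PR9692 by a median of 1.42. That drop was not particular to them, since 22 of the 27 had a lower mean in PR9692-E9 than in PR9692. The 20 probe sets besides those 7 were not under 4 throughout, and 8 of the 27 had a higher mean in PR9692-E9-EGR1 than in PR9692. These 8 came from NEDD4L, LOC426615 and LOC431003 alone, of 12 W-linked genes tested, named after their values were seen. Both counts go against loss of the whole W chromosome unless these probe sets also read copies elsewhere. The sources used here do not tell this, so loss of the W remains open. Cells from a male bird would also lack the W. Such an origin would go against the label, which derives this line from PR9692-E9, where HINTW read 13.33. The W-linked counts alone leave it open for the same reason. A second Z could raise Z-linked genes, but the size of such a rise in these cells is not known. The Z-linked values showed no clear rise, with intervals against both other lines that included 0, and cannot decide this alone. Z-linked genes (369) differed from autosomal genes (7615) by a median of -0.00987 in PR9692-E9-EGR1 against PR9692-E9 (95% bootstrap interval -0.09 to 0.06), 0.10 against PR9692 (-0.01 to 0.21) and -0.10 in PR9692 against PR9692-E9 (-0.17 to -0.05).

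Genes of chromosomes 5, 7, 15 and 18 were higher in PR9692 than in PR9692-E9, with median differences of 0.31, 0.32, 0.44 and 0.38 and with 57, 54, 34 and 22 genes that rose against 7, 1, 0 and 1 that fell. They were chosen for the lowest p among 30 chromosomes (camera adjusted p = 1.1e-07, 3.0e-08, 1.1e-09 and 4.8e-08, and 0.0591, 0.0477, 0.0222 and 0.00636 with an estimated correlation), of which 11 were called and 7 with an estimated correlation, the other 4 of these being chromosomes 13, 22, 27 and 34, which were lower. Small chromosomes were taken as 11 to 28, so only 15 and 18 of these 4 were small. The other 16 small chromosomes had a median shift of -0.13, and 3 of their medians lay above 0. This argues against an upward bias shared by small chromosomes and says nothing about chromosomes 5 and 7. No single array carried the pattern, since the smallest median without any 1 of the 6 arrays was 0.25. A difference in chromosome copy number may underlie it, but DNA was not analysed here. The smallest median among 4 equal parts of each of them was 0.19, which a shift along a whole chromosome would give whatever its cause. In PR9692-E9-EGR1 against PR9692-E9 the medians of chromosomes 5, 7, 15 and 18 were 0.02, 0.06, 0.04 and -0.16, and camera called none. Against PR9692 they were -0.30, -0.24, -0.28 and -0.51. Camera called all of these, but only chromosome 18 with an estimated correlation. COL6A3, COL6A1 and ITGA4 lie on chromosome 7, and their differences were far larger than its median of 0.32.

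Other splits of the 6 arrays of each comparison into 3 and 3 number 10, too few for a share under 0.05. The real splits gave 1689, 4342 and 5748 changed probe sets, in 1 of 10 splits each, and the highest other split gave 0. For gene lists, 2, 6 and 9 of 10 splits gave as many as the real 6, 2 and 2, with highest others of 6, 5 and 8. Of 100 splits of the 9 arrays into a shared control and 2 groups, 3, the real one included, gave at least the 622 probe sets changed the same way. This share is under 0.05, but splits that mix the lines widen the spread within groups and can give 0. It therefore shows only that the lines differ. It cannot tell whether the sharing between both metastatic lines exceeds what a shared control gives. The highest other was 2877 and the next 1783. The 2877 came from the real 3 lines with PR9692-E9-EGR1 in place of PR9692-E9 as the shared control. PR9692 and PR9692-E9 thus shared more changes against PR9692-E9-EGR1 than the 622 of both metastatic lines against PR9692-E9. Both of these splits took the 3 PR9692-E9-EGR1 arrays as the shared control. This points to a structure of the samples, namely that this line stands apart from the other 6 arrays.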
